A study of Homo sapiens with 24 samples.

How the data were processed

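RNA levels were measured on 24 Affymetrix HG-U133 Plus 2 arrays, 3 in each of 8 groups. Per the labels' protocols, monocytes were prepared from buffy coats of 3 donors and either lysed or cultured with 50 ng/ml GM-CSF, which was washed off after 4 h. Microvesicles were pelleted from the medium by centrifugation for 30 min and put for 24 h on new monocytes, of which a fraction was lysed as the recipient group, per the labels' protocols. THP1, a human monocytic leukaemia line, was treated with DMSO or 65 nM PMA, and the vesicles of either culture were put for 24 h on new THP1 cells, per the labels' protocols. RNA of donor monocytes and GM-CSF macrophages (6 arrays) was labelled with a One-Cycle kit from 2 ug and RNA of the other 6 groups (18 arrays) with Ovation kits from 30 ng, per the labels' protocols. The labels of the recipient group conflict, since title and cell type name freshly isolated monocytes and the treatment field names differentiated macrophages. The group was kept as titled.

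The deposited values are log2 probe-set signals made by the authors. Partek, RMA and GCRMA are named without version, role or order, per the submitters' processing notes. The deposited log2 values pile up near the floor as after a background adjustment, and their 75th percentile was 8.82 to 9.14 on the 18 Ovation arrays. On the 6 One-Cycle arrays it split by group, up to 6.29 in donor monocytes and 6.84 to 6.93 in GM-CSF macrophages. Values below log2 3 were treated as near background. All 24 arrays were used. Their number, 3 per group, limits the precision.

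The platform table holds 54675 probe sets, 62 of them controls. It assigns 41097 to 1 gene, 1801 to several genes and 11777 to none, and probe sets of several genes or none were left out. Of the 41091 single-gene probe sets that are not controls, 41037 had a gene identifier in the RefSeq gene table. XIST, TSIX and Y-linked genes (59 probe sets) were left out of every test because part of the arrays come from blood donors. For each of the remaining 19740 genes the probe set with the highest mean over the 24 arrays was used. A gene was tested if its value lay above the 40th percentile of all probe sets of a fit in at least 3 of the 12 arrays (log2 2.54 in primary cells and 2.52 in THP1), which left 15251 genes in primary cells and 14077 in THP1. CD14 and CD68 did not reach a test in THP1.

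Primary cells and THP1 were fitted apart in limma 3.58.1 under R 4.3.3, each with 4 groups of 3 arrays and 1 shared estimate of spread per gene, and contrasts of group means were tested with moderated statistics and Benjamini-Hochberg adjustment at 0.05. The 5 main comparisons were GM-CSF macrophages with donor monocytes, vesicle-treated cells with recipient arrays, PMA with DMSO, PMA microvesicles with DMSO microvesicles, and DMSO microvesicles with DMSO donors. Differences of responses were tested as contrasts of contrasts in each fit, and recipient with donor monocytes as a measure of the joint difference of donors and kit. The 27 gene lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment within a comparison, again with the correlation estimated per list, and with the rotation test fry. The lists were markers of monocytes, macrophages, T cells, B cells, natural killer cells, platelets, erythroid cells and neutrophils. The others were adhesion genes, inflammatory cytokines, NF-kB targets, the interferon response, immediate early genes, GM-CSF and STAT5 signalling, antigen presentation, complement, the lysosome, cholesterol synthesis, lipid efflux, glycolysis and hypoxia, oxidative phosphorylation, metallothioneins, the cell cycle, the unfolded protein response, heat shock, matrix proteases and targets of miR-223. The list called lipid efflux also covers genes of the nuclear receptor LXR, and members such as CD36 and SCD do not export lipid. Of the 468 entries of the lists 433 were measured. Log2 differences of pairs of comparisons that share no array were correlated across genes, which are not independent replicates, and overlaps of calls were set against the number independent lists would share (Fisher test).

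The groups, tests, filter, lists, alternatives and the rule for named genes were fixed before the data were examined. Per comparison the rule takes the 6 largest and 6 smallest differences among genes called with no overlap between groups, the 3 called members of each list with the largest differences (where none is called, the member with the highest mean), and CD14, ITGAM, ITGAX, CSF1R, CSF2RA, MYC and CD68. For the differences of responses it takes the 4 largest and 4 smallest. Immunoglobulin and T cell receptor segments and genes with common whole-gene or expression polymorphisms are not named. After the values were seen, list members in the text were limited to lists that passed camera, and other lists are given as counts. Genes named for the recipient arrays come from this rule too, except MRC1 and OLR1, which it named for the GM-CSF comparison. Of the 91 named genes with GM-CSF 48 had several probe sets, as had 28 of 45 with macrophage microvesicles and 50 of 82 with PMA. The same held for 43 of 71 with PMA microvesicles and 25 of 44 with DMSO microvesicles. Probe sets of 1 gene differed in direction for 10, 8, 12, 5 and 6 of these genes, in the same order. Most probe sets went against the main one for 1 gene with macrophage microvesicles and 2 with PMA.

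The groups share replicate numbers, so a fit of the groups compared with the number as a block was run for each comparison. Whether the numbers pair the arrays was checked by the correlation of deviations from the group means for numbers 1, 2 and 3. It was 0.52, 0.54 and 0.15 for PMA against DMSO microvesicles and 0.50, 0.15 and 0.13 for DMSO microvesicles against DMSO donors, each above 0.1, and the numbers were taken to pair these arrays. Arrays of different numbers reached 0.48 and 0.52 in these comparisons, so this pairing is uncertain. GM-CSF macrophages and donor monocytes come from the same 3 donors, per the labels' protocols, although the correlations were 0.04, 0.11 and -0.00. For vesicle-treated cells and recipient arrays they were -0.13, 0.22 and 0.05 and no label says that the numbers mark donors, and for PMA against DMSO they were 0.09, 0.07 and 0.35.

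Alternatives covered the filter (none, or the 60th percentile), the probe sets (the mean per gene, each by itself, or without those ending in _x_at or _s_at) and the scaling (each array centred on its median, or quantile normalization of all 24 arrays). Others were the arrays in the fit, an intensity trend with a robust prior, the block, stricter thresholds, other control groups, and each array left out in turn. Leaving out replicate 1 of THP1 with PMA microvesicles from comparisons that do not use it, and a comparison of the GM-CSF with the PMA response, were added after the data were seen.

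The pipeline was tested on simulated data with the real arrays' means and spread, in which 200 genes were changed. Changes of log2 1 and log2 2 were recovered for 33% and 72% of them with GM-CSF, 35.5% and 77.5% with macrophage microvesicles, 25% and 47% with PMA, 16.5% and 39.5% with PMA microvesicles, and 16% and 41.5% with DMSO microvesicles. For the differences of responses the shares were 23.5% and 55% in primary cells and 11% and 29.5% in THP1, and for recipient against donor monocytes 44% and 68%. No changed gene was called in the wrong direction, and up to 10 unchanged genes were called in a run. A raised list was called in each of the 8 comparisons, with at most 1 other list. The simulated noise was independent between genes, so this does not test false list calls among correlated genes.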

Results

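RNA of human monocytes, of macrophages and of the monocytic leukaemia line THP1 was profiled on 24 Affymetrix HG-U133 Plus 2 arrays, in 8 groups of 3. Microvesicles, the membrane-bound particles that cells shed, were spun from culture medium and put on new cells, and the question was how far cells given macrophage microvesicles came to resemble macrophages. In primary cells the groups were fresh blood monocytes of 3 donors, the macrophages made from them with the growth factor GM-CSF, monocytes set aside as vesicle recipients, and such cells after 24 h with microvesicles from the GM-CSF macrophages. In THP1 the groups were cells given the solvent DMSO, cells given the differentiating agent PMA at 65 nM, and new THP1 cells after 24 h with the microvesicles of either culture. RNA of the first 2 groups was labelled with a One-Cycle kit from 2 ug and RNA of the other 6 groups with Ovation kits from 30 ng. The upper quartile of log2 signal was up to 6.29 in donor monocytes, 6.84 to 6.93 in GM-CSF macrophages and 8.82 to 9.14 on the 18 Ovation arrays. On the One-Cycle and Ovation arrays, 56.7% to 57.8% against 47.8% to 51.4% of probe sets read below log2 3. Primary cells and THP1 cells were fitted apart. The fit of primary cells holds 6 arrays of either kit with 1 shared spread per gene, and each main comparison stayed within 1 kit. The number of arrays, 3 per group, limits the precision.

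The arrays of donor monocytes resembled each other closely (mean correlation of an array with its group 0.991 to 0.992), and so did those of GM-CSF macrophages (0.973 to 0.984). The arrays titled as recipient monocytes resembled the vesicle-treated cells (0.959 to 0.970) as much as each other (0.957 to 0.958), and correlated with donor monocytes at 0.760 to 0.817. In THP1, component 1 parted the PMA side from the DMSO side and held 58.6% of the variance. Replicate 1 of THP1 with PMA microvesicles lay on the DMSO side: it correlated at 0.864 with its own group, 0.934 with DMSO donors and 0.946 with THP1 given DMSO microvesicles. Its difference between the 3' and 5' control probe sets of ACTB was 1.37 log2, against 0.77 and 0.74 in the other 2 arrays of its group.

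**Figure D1:**
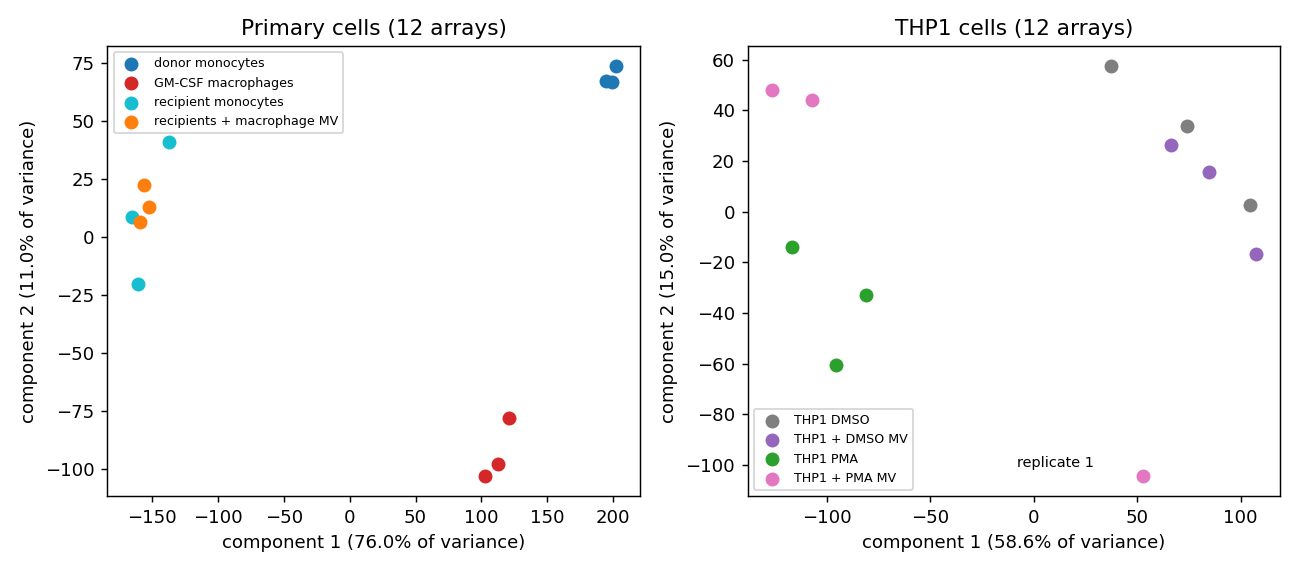
Principal components of the log2 values of the tested genes, 1 point per array, for the 12 arrays of primary cells (left) and the 12 arrays of THP1 cells (right). Axes give component scores with the share of variance in percent, colours give the 8 groups of 3 arrays, and MV stands for microvesicles.

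The recipient arrays did not read as fresh monocytes. Their title and cell type say freshly isolated monocytes, while their treatment label says differentiated macrophages, so the labels conflict. Of the 25 macrophage markers measured, 21 were higher there than in donor monocytes and 0 lower, with a median difference of 6.48 log2 where the median of all genes was 1.23. MRC1, the mannose receptor, SPP1, the secreted protein osteopontin, and OLR1, a receptor for oxidised LDL, read at or near the level of the GM-CSF macrophages. SPP1 was 14.06 ± 1.55 (SD, n = 3) in the recipient arrays, 2.72 ± 0.05 in donor monocytes and 14.26 ± 0.27 in GM-CSF macrophages. The lipid-binding protein APOC1 stood at 15.03 ± 0.31 against 2.30 ± 0.39 in donor monocytes. The glutamate transporter SLC1A3 was higher by 10.25 ± 0.42 (SE) and GPNMB, a membrane glycoprotein of macrophages, by 11.60 ± 0.65. Lower in the recipient arrays were RETN, which encodes resistin (-8.53 ± 1.68), the sphingosine phosphate receptor S1PR4 and the arginine deiminase PADI4. A group mean below log2 3, near background, was found for 4 of the 6 largest rises and for 6 of the 6 largest falls. The size and rank of these differences are therefore uncertain. In all, 11946 of 15251 genes differed, 8393 higher and 3553 lower, but donors and labelling kit differ too, and the split moved with the scaling. The ACTB difference between 3' and 5' control probe sets was 1.64 ± 0.59 (SD, n = 3) in recipient and 0.28 ± 0.04 in donor arrays. Centring each array on its median gave 7405 higher and 5038 lower (median of all genes 0.74), and quantile normalization of all arrays gave 4914 higher and 5717 lower (median -0.09). The comparison of vesicle-treated cells with these arrays is therefore one between cells that both carry macrophage markers.

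**Figure D2:**
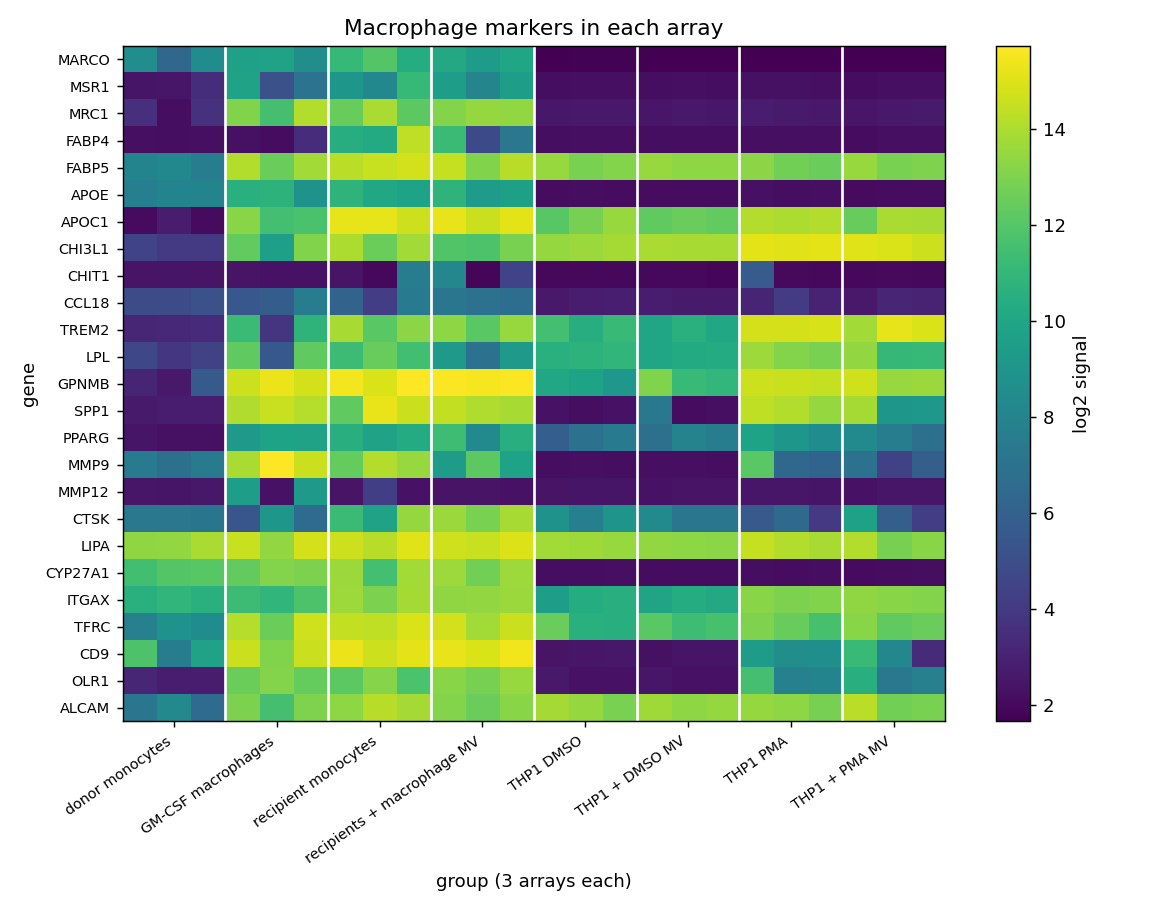
Log2 signal (colour) of each measured macrophage marker (vertical axis) in each of the 24 arrays (horizontal axis), in blocks of the 3 arrays of a group. MV stands for microvesicles.

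GM-CSF macrophages were compared with the fresh monocytes of the donors they came from. The largest rises were in macrophage genes: SPP1 rose by 11.54 ± 0.61 (SE from the shared spread, n = 3 against 3), GPNMB by 11.16 ± 0.65, APOC1 by 9.85 ± 0.43, OLR1 by 9.85 ± 0.37 and MRC1 by 9.75 ± 0.69, followed by COXFA4L3 at 9.20 ± 0.69. The largest falls were those of NAPSB (-9.08 ± 1.02) and IFITM1, an interferon-induced antiviral membrane protein (-8.35 ± 0.44). SECTM1 (-8.35 ± 1.04), CFP, the complement regulator properdin (-8.24 ± 1.58), the transcription factor NFE2 (-8.14 ± 1.19) and F13A1, the coagulation factor XIII A chain (-7.98 ± 0.86), fell as well. MYC, a growth-promoting transcription factor, rose by 5.99 ± 0.88 and CSF2RA, the GM-CSF receptor alpha chain, fell by 1.34 ± 0.32. CD14 (-0.28 ± 0.22), the integrin chains ITGAM (0.09 ± 0.40) and ITGAX (0.63 ± 0.27) and the M-CSF receptor CSF1R (-0.58 ± 0.51) did not pass the test, with adjusted p from 0.0782 to 0.902. Of the 12 genes with the largest differences 5 had a group mean below log2 3, near background, which leaves the size and rank of their differences uncertain. The same held for 4, 8, 9 and 7 of 12 in the comparisons of macrophage microvesicles, PMA, PMA microvesicles and DMSO microvesicles below. For each gene named here or below as risen or fallen in a main comparison, all 3 arrays of one group lay above all 3 of the other, which chance gives for 10% of genes. List members given only as counts were not held to this. ITGAX has 1 probe set on each side of 0 here, and 1 of the 4 probe sets of ABCA1, named next, was lower.

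Of the 25 macrophage markers 17 rose and 0 fell, with a median of 5.18 (adjusted p = 3.57e-08, and adjusted p = 0.162 with an estimated correlation). Cholesterol synthesis rose with them: 13 of 15 genes, among them the sterol transfer protein STARD4 (6.78 ± 0.76), the enzymes MSMO1 (6.46 ± 0.45) and SQLE (5.84 ± 0.72), at an adjusted p of 3.13e-07 (adjusted p = 0.322 with an estimated correlation). Of the 14 genes on the list of lipid efflux and LXR 8 rose, such as the desaturase SCD (6.99 ± 0.42) and the cholesterol exporter ABCA1 (6.36 ± 0.87), with adjusted p = 0.00665, and adjusted p = 0.322 with an estimated correlation. The lysosome list had 10 of 22 members up and 1 down, and 11 and 1 when adjusted over the list alone, with the protease CTSL at 3.76 ± 0.35 and the cholesterol transporter NPC1 at 3.40 ± 0.40 (adjusted p = 0.00689, and adjusted p = 0.53 with an estimated correlation). Of the 10 heat shock genes, 6 rose, HSPH1 by 2.62 ± 0.32 and HSPE1 by 2.52 ± 0.28, and 2 fell, among them HSPA6 at -3.11 ± 0.91 (adjusted p = 0.0295, and adjusted p = 0.322 with an estimated correlation). Oxidative phosphorylation had 8 of 17 members up, such as COX6C at 1.77 ± 0.36, at an adjusted p of 0.0425, and adjusted p = 0.719 with an estimated correlation. That list passed under 7 of its 19 alternatives (adjusted p from 1.14e-05 to 0.719) and missed the threshold without GM-CSF macrophage array 1 (adjusted p = 0.104) or 3 (0.12), without donor monocyte array 1 (0.0703), 2 (0.0693) or 3 (0.0504), and with the donor as a block (0.0973).

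Among the falling groups, 18 of 23 interferon response genes fell and 1 rose, or 19 and 1 when adjusted over the list alone. OASL fell by 6.31 ± 0.78, IFI44L by 6.29 ± 0.61 and MX1, an antiviral GTPase, by 5.06 ± 0.67. The list had a median of -2.94 and an adjusted p of 9.56e-06 (adjusted p = 0.374 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation, fell in 13 of 18 cases and rose in 1, with the phosphatase DUSP1 at -6.08 ± 0.58 and the nuclear receptors NR4A2 at -5.20 ± 0.33 and NR4A1 at -4.97 ± 0.55 (adjusted p = 0.000128, and adjusted p = 0.162 with an estimated correlation). Of the 15 monocyte markers 8 fell, 9 when adjusted over the list alone, the strongest S100A12 (-7.22 ± 1.99), VNN2 (-6.92 ± 0.85) and the fractalkine receptor CX3CR1 (-5.55 ± 1.34). That list had an adjusted p of 0.0329, adjusted p = 0.505 with an estimated correlation and adjusted p = 0.0848 with quantile normalization, within a range of 0.00208 to 0.505 over its 19 alternatives. Platelet markers fell in 4 of 9 cases, the chemokine PF4 at -5.62 ± 0.19 and the tubulin TUBB1 at -5.02 ± 0.70 (adjusted p = 0.0295, and adjusted p = 0.471 with an estimated correlation). The list missed the threshold without donor monocyte array 1 (adjusted p = 0.155) or 2 (0.225), within 0.000127 to 0.471 over its 19 alternatives. The other 17 lists did not pass, with adjusted p from 0.0528 to 0.889. Of these, inflammatory cytokines had 5 of 21 members up (3 when adjusted over the list alone), and the GM-CSF and STAT5 list 6 of 14 down. Antigen presentation had 4 of 16 down (2 when adjusted over the list alone) and complement 2 up and 7 down of 13 (2 and 9 when adjusted over the list alone). Adhesion genes had 4 of 20 up and 7 down, glycolysis and hypoxia 3 up and 1 down of 21 (2 and 1 when adjusted over the list alone), and the miR-223 targets 7 up and 5 down of 20 (adjusted p = 0.614 for each of the 3). The miR-223 list was tested as up with a median of -0.06 and a mean of -0.13, and the glycolysis list as up with a median of 0.04 and a mean of -0.10. Erythroid markers had 3 of 4 down and neutrophil markers 4 of 9 down, with adjusted p of 0.0597 and 0.0917. Natural killer cell markers had 3 of 11 down, 2 when adjusted over the list alone (median -1.24, adjusted p = 0.0834, within 0.00138 to 0.351 over 19 alternatives). T cell markers had 2 of 10 down and B cell markers 1 of 8, with adjusted p of 0.268 and 0.782. With the donor as a block the inflammatory cytokine (adjusted p = 0.0265), GM-CSF and STAT5 (0.0265) and complement (0.0433) lists passed, within 0.00159 to 0.323, 0.00159 to 0.53 and 0.0094 to 0.536 over their 19 alternatives.

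In the test across all genes, 6976 of 15251 passed, 3342 up and 3634 down, and 4278 of them changed at least 2-fold. This fit did not pair the arrays by donor. With the donor as a block 2 of the 40 named genes called lost their call. The upper quartile of signal differed between these groups, at 6.84 to 6.93 against 6.29 or less. With each array centred on its median, which moved the median of all genes from -0.11 to 0.003, the split was 3460 up and 1886 down of 5346. Without the filter it was 3380 up and 6663 down of 10043.

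Cells given macrophage microvesicles were compared with the recipient arrays. By the titles, no group holds monocytes cultured for 24 h without vesicles, so effects of vesicles and of culture cannot be told apart. Interferon response genes rose: the chemokine CXCL10 by 5.81 ± 0.65 (SE, n = 3 against 3), RSAD2, which encodes viperin, by 4.66 ± 0.68 and IFI44L by 3.84 ± 0.61. Natural killer cell markers rose as well, GNLY by 5.72 ± 0.54, PRF1, the pore-forming perforin, by 5.45 ± 0.68 and the granzyme GZMA by 4.87 ± 0.37. The receptor tyrosine kinase AXL (6.25 ± 0.87), LEP, the hormone leptin (6.21 ± 1.10), and the matrix protein MFAP5 (5.78 ± 0.65) completed the 6 largest rises. The largest falls were in SPRY2, an inhibitor of growth factor signalling (-5.31 ± 0.96), MSC-AS1 (-5.13 ± 0.89), TFPI, the inhibitor of tissue factor (-4.96 ± 0.77), ZFP57 (-4.92 ± 0.88), the thyroid hormone receptor THRB (-4.77 ± 0.24) and the adhesion molecule NCAM1 (-4.45 ± 0.42). Of the 25 macrophage markers 0 passed, with a median of -0.09 and a mean of -0.39. CD14 (-0.46 ± 0.22), ITGAM (-0.60 ± 0.40), ITGAX (0.01 ± 0.27), CSF1R (-0.53 ± 0.51), CSF2RA (0.66 ± 0.32) and MYC (-0.90 ± 0.88) did not pass either.

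Of the 23 interferon response genes 4 rose, 13 when adjusted over the list alone, with a median of 1.58 (adjusted p = 4.9e-21, and adjusted p = 0.0805 with an estimated correlation). These counts were 2 and 8 without vesicle-treated array 1, and 3 and 8 without recipient array 2. The natural killer cell list had 4 of 11 members up and NCAM1 down, or 9 and 1 when adjusted over the list alone. It had a median of 4.09, an adjusted p of 2.97e-13 and adjusted p = 0.00265 with an estimated correlation. It was the only list in the 5 main comparisons to keep its call with that correlation and passed without each of the 6 arrays in turn. T cell markers had 1 of 10 members up, CD8A by 4.54 ± 0.31, or 2 when adjusted over the list alone (adjusted p = 1.74e-05, and adjusted p = 0.0666 with an estimated correlation), and their median of 1.33 was 0.49 without vesicle-treated array 3. B cell markers had 0 of 8 called and an adjusted p of 0.856. Cell cycle genes were lower, with 1 of 24 called, the cyclin CCNB2 at -3.50 ± 0.45, and 13 when adjusted over the list alone, at a median of -2.17 and an adjusted p of 9.17e-12 (adjusted p = 0.474 with an estimated correlation). Of these, 15 fell without recipient array 1 (median -3.14), 1 without recipient array 2 (median -1.35) and 4 without recipient array 3. Cholesterol synthesis had 1 of 15 called, the mevalonate kinase MVK at -2.07 ± 0.33, and 2 when adjusted over the list alone (adjusted p = 0.00122, and adjusted p = 0.795 with an estimated correlation). That list missed the threshold without vesicle-treated array 1 (adjusted p = 0.0769) or recipient array 2 (adjusted p = 0.328), within 3.54e-06 to 0.795 over its 20 alternatives. The other 22 lists did not pass, with adjusted p from 0.0529 to 0.949, and the 20 miR-223 targets held 0 called genes.

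In total 118 of 15251 genes passed, 53 up and 65 down. With each array centred on its median, which moved the median of all genes from -0.03 to -0.15, 49 rose and 114 fell. The labels do not say whether the replicate numbers of these groups mark donors. With the number as a block, in a fit of only these 2 groups, limma called 0 genes (1058 at an unadjusted p below 0.05). The fit of only these 2 groups without the block, which is the like comparison, called 7. In the main fit of 4 groups 1955 lay at an unadjusted p below 0.05. The smallest SD of the difference between 2 arrays of a group was 0.99 in recipients and 0.65 in vesicle-treated cells. It was 0.35 in donor monocytes and in GM-CSF macrophages. The spread shared by the 4 groups may therefore be too small for this comparison. Without recipient array 1, 2 or 3 the count was 292, 316 or 469. With both groups titled as fresh monocytes as the control, 9838 genes passed and none of the 5 lists did.

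**Figure D3:**
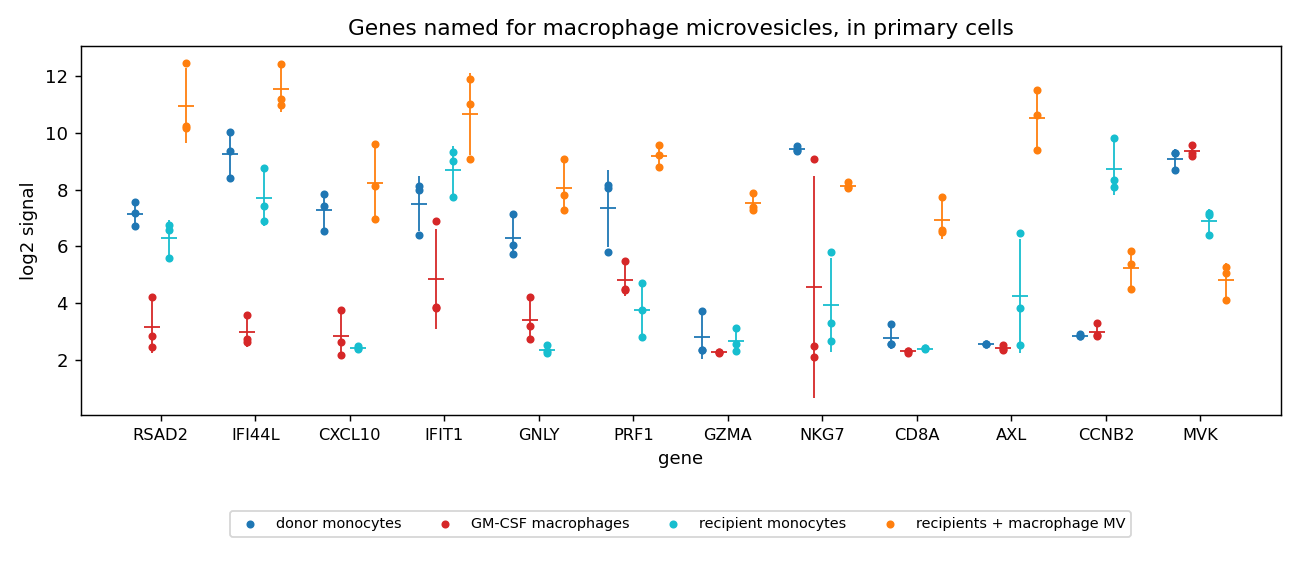
Log2 signal of 12 genes named for the vesicle-treated cells or in their lists, in the 4 groups of primary cells. Points are single arrays, and dashes with bars are the mean and SD of 3 arrays.

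PMA-treated THP1 cells were compared with THP1 cells in DMSO. SPP1 rose by 11.73 ± 1.55 (SE, n = 3 against 3), RIN2, a regulator of endocytosis, by 10.29 ± 0.74, the intermediate filament NES by 10.08 ± 0.38, FNDC1 by 10.03 ± 0.20, the homeobox gene DLX3 by 9.79 ± 0.47 and GNLY by 9.77 ± 0.73. MS4A3 fell by 7.31 ± 0.98 and S100A8, a calcium-binding protein of monocytes and neutrophils, by 7.21 ± 1.19. The cytokine receptor IL31RA (-8.09 ± 0.70), ANKRD55 (-7.74 ± 0.89), KLHDC7B (-7.51 ± 1.53) and the calcium channel subunit CACNA2D3 (-6.81 ± 1.29) completed the 6 largest falls. The integrin chains ITGAM (2.35 ± 0.26) and ITGAX (2.97 ± 0.24) and the receptor CSF1R (2.28 ± 0.38) rose, while CSF2RA (-2.46 ± 0.26) and MYC (-0.90 ± 0.25) fell. The difference between the 3' and 5' control probe sets of ACTB, a sign of RNA quality, was 0.78 ± 0.27 (SD, n = 3) with PMA and 1.18 ± 0.15 with DMSO.

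Macrophage markers rose in 10 of 18 cases, with 12 up and 1 down when adjusted over the list alone, with SPP1 among them and OLR1 at 6.69 ± 1.04 (adjusted p = 1.4e-05, and adjusted p = 0.159 with an estimated correlation). Of the 19 adhesion genes 14 rose and 1 fell, with the integrin chains ITGB7 at 5.58 ± 0.36 and ITGB5 at 4.37 ± 0.36 and the adhesion receptor ICAM1 at 3.47 ± 0.62 (adjusted p = 1.23e-05, and adjusted p = 0.128 with an estimated correlation). Interferon response genes rose in 14 of 23 cases and fell in 1, or 15 and 1 when adjusted over the list alone, OAS1 by 6.31 ± 0.72, IFI44 by 5.69 ± 1.11 and IFI27 by 5.54 ± 0.61 (adjusted p = 1.27e-08, and adjusted p = 0.0982 with an estimated correlation). Metallothioneins rose in 5 of 6 cases, MT2A by 3.42 ± 0.47, at an adjusted p of 0.000755 (adjusted p = 0.321 with an estimated correlation). Of the 15 matrix proteases and their inhibitors 7 rose and 2 fell, or 8 and 2 when adjusted over the list alone, with MMP1 at 8.23 ± 0.25, MMP7 at 5.57 ± 0.54 and MMP14 at 3.13 ± 0.25 (adjusted p = 0.00588, and adjusted p = 0.262 with an estimated correlation). Lipid efflux had 3 of 13 up, 5 when adjusted over the list alone, led by the scavenger receptor CD36 at 7.14 ± 1.28 (adjusted p = 0.0159, and adjusted p = 0.24 with an estimated correlation). The lysosome list had 4 of 21 up, 5 when adjusted over the list alone, CTSB by 1.16 ± 0.14 among them, at an adjusted p of 0.0324 and adjusted p = 0.458 with an estimated correlation. It missed the threshold without PMA array 1 (adjusted p = 0.116) or DMSO array 1 (adjusted p = 0.0997), within 0.000251 to 0.458 over its 20 alternatives.

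Cell cycle genes fell in 13 of 25 cases, the kinases TTK at -3.72 ± 0.93 and BUB1 at -2.18 ± 0.41 and the topoisomerase TOP2A at -2.16 ± 0.31 (adjusted p = 1.4e-05, and adjusted p = 0.24 with an estimated correlation). Of the 14 unfolded protein response genes 8 fell and 1 rose, or 10 and 1 when adjusted over the list alone, with ASNS at -2.56 ± 0.33 and DNAJB9 at -1.58 ± 0.48 (adjusted p = 0.000199, and adjusted p = 0.0628 with an estimated correlation). Heat shock genes fell in 4 of 10 cases, 5 when adjusted over the list alone, HSPA6 at -5.65 ± 0.87 (adjusted p = 0.0124, and adjusted p = 0.24 with an estimated correlation). Targets of miR-223, a microRNA of myeloid cells, fell in 4 of 20 cases, the transcription factors FOXO1 at -3.69 ± 0.96 and NFIA at -3.60 ± 0.70 among them, at an adjusted p of 0.00393 (adjusted p = 0.24 with an estimated correlation). IGF1R, also a target, fell by 2.03 ± 0.40 on its main probe set, but 3 of its 5 probe sets were higher. The other 16 lists did not pass, with adjusted p from 0.0595 to 0.865. In total 3111 of 14077 genes passed, 1524 up and 1587 down, 2690 of them at least 2-fold. The count was 1839 without PMA array 3, 1876 without DMSO array 1, 1764 without DMSO array 2, and 4722 with only the 2 groups in the fit. It was 5856 without replicate 1 of THP1 with PMA microvesicles, an array that enters here only through the shared spread and was left out after its values were seen. Without it the lists called with PMA kept their calls. The lysosome then had 9 members up, lipid efflux 7 up, heat shock 7 down and the miR-223 targets 1 up and 8 down.

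THP1 cells given microvesicles of PMA-treated cells were compared with those given microvesicles of DMSO-treated cells. RIN2 rose by 9.62 ± 0.74 (SE, n = 3 against 3), DLX3 by 9.45 ± 0.47, GSG1 by 9.34 ± 0.71, FNDC1 by 8.97 ± 0.20, the proteoglycan CSPG4 by 8.46 ± 0.82 and the oxygen carrier MB by 8.32 ± 0.71. IL31RA fell by 7.36 ± 0.70, S100A8 by 6.78 ± 1.19, WDR49 by 6.67 ± 0.17, the sialic acid receptor SIGLEC6 by 6.44 ± 0.90, the splicing factor ESRP1 by 6.21 ± 0.66 and ANKRD55 by 6.16 ± 0.89. ITGAM (2.01 ± 0.26), ITGAX (3.13 ± 0.24) and CSF1R (3.78 ± 0.38) rose and MYC (-0.91 ± 0.25) fell, while CSF2RA (-0.66 ± 0.26) did not pass. The ACTB difference was 0.77 and 0.74 in replicates 2 and 3 and 1.37 in replicate 1 with PMA microvesicles, against 1.34 ± 0.07 (SD, n = 3) with DMSO microvesicles. These are the responses of cells that had met only vesicle preparations, but no group received a preparation made from PMA medium without cells.

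Macrophage markers rose in 6 of 18 cases, 8 when adjusted over the list alone, with SPP1 at 6.80 ± 1.55, OLR1 at 6.13 ± 1.04 and the lipid receptor TREM2 at 4.44 ± 0.38 (adjusted p = 0.00014, and adjusted p = 0.189 with an estimated correlation). Of the 19 adhesion genes 9 rose and 1 fell, or 10 and 2 when adjusted over the list alone, ITGB7 by 4.81 ± 0.36 and ICAM1 by 4.24 ± 0.62, while the selectin ligand SELPLG fell by 3.33 ± 0.45 (adjusted p = 0.00014, and adjusted p = 0.189 with an estimated correlation). Interferon response genes rose in 9 of 23 cases, with 9 up and 1 down when adjusted over the list alone, IFI27 by 4.62 ± 0.61, OAS1 by 4.58 ± 0.72 and IRF7 by 3.64 ± 0.42 (adjusted p = 0.00014, and adjusted p = 0.189 with an estimated correlation). Inflammatory cytokines rose in 3 of 17 cases, with 4 up and 1 down when adjusted over the list alone, CCL4 by 5.51 ± 0.84 and IL1B by 5.09 ± 0.62. NF-kB targets rose in 2 of 16 cases, IER3 by 5.19 ± 1.07 and NFKBIE by 1.64 ± 0.38, and 5 when adjusted over the list alone. Their adjusted p were 0.0246 and 0.0191, each with adjusted p = 0.316 with an estimated correlation. Of the lysosome list 5 of 21 rose, 9 when adjusted over the list alone, the sialidase NEU1 by 1.84 ± 0.33 (adjusted p = 0.00482, and adjusted p = 0.316 with an estimated correlation). Among matrix proteases 7 of 15 rose, such as MMP14 at 3.67 ± 0.25 and MMP7 at 3.54 ± 0.54, and 3 fell, such as the urokinase PLAU at -2.85 ± 0.48 (adjusted p = 0.0309, and adjusted p = 0.36 with an estimated correlation). Lipid efflux had 2 of 13 up, 3 when adjusted over the list alone, CD36 by 5.93 ± 1.28 (adjusted p = 0.0309, and adjusted p = 0.316 with an estimated correlation). Metallothioneins had 1 of 6 up, MT2A by 1.75 ± 0.47, and 5 when adjusted over the list alone (adjusted p = 0.00482, and adjusted p = 0.36 with an estimated correlation).

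Immediate early genes had 2 of 18 up, DUSP2 by 3.53 ± 0.61 and EGR1 by 1.48 ± 0.37 (adjusted p = 0.0258, and adjusted p = 0.462 with an estimated correlation). Platelet markers had 2 of 8 up, TREML1 from 2.57 ± 0.03 to 9.48 ± 1.07 (SD, n = 3) and MYL9 by 2.87 ± 0.44, and B cell markers 1 of 8, CD22 by 4.48 ± 0.54. Their adjusted p were 0.00793 and 0.0249, with adjusted p = 0.189 and 0.393 with an estimated correlation. Cell cycle genes fell in 10 of 25 cases, 12 when adjusted over the list alone, with TTK at -3.54 ± 0.93 and TOP2A at -1.73 ± 0.31 (adjusted p = 0.000271, and adjusted p = 0.316 with an estimated correlation). Of the unfolded protein response list 3 of 14 fell, 4 when adjusted over the list alone, EDEM1 at -1.16 ± 0.31 and DDIT3 at -1.01 ± 0.25 (adjusted p = 0.0309, and adjusted p = 0.189 with an estimated correlation). The miR-223 targets had 1 of 20 down, ECT2 at -2.32 ± 0.64, and 0 when adjusted over the list alone, at an adjusted p of 0.00949 and adjusted p = 0.307 with an estimated correlation. Replicate 1 of the PMA microvesicle group, the array on the DMSO side, bears on each of these groups. Without it none of the 15 lists passed (lowest adjusted p 0.11), although most held more called members. Macrophage markers then had 9 up and 1 down, adhesion genes 10 and 4, the interferon list 9 and 2, inflammatory cytokines 6 and 0, NF-kB targets 8 and 3 and immediate early genes 5 and 2. The lysosome had 10 up and 4 down, lipid efflux 8 and 1, metallothioneins 5 and 0, platelet markers 3 and 0 and B cell markers 4 and 0. The exporters ABCA1 (-0.97 ± 0.61, limma adjusted p = 0.199) and ABCG1 (-0.18 ± 1.01, limma adjusted p = 0.891) then did not pass. Cell cycle genes had 4 up and 12 down, the unfolded protein response 3 and 6 and the miR-223 targets 1 and 11. Medians shrank for the interferon list (1.53 to 0.55 over the 22 members then tested) and inflammatory cytokines (0.49 to 0.15). They grew for lipid efflux (0.87 to 1.54), B cell markers (1.44 to 2.28), metallothioneins (1.33 to 1.48) and the miR-223 targets (-0.78 to -0.90). The median of platelet markers went from 0.34 over 8 members to 0.82 over the 6 then tested. Differences smaller without it were those of SPP1 (5.23), OLR1 (5.14), CD36 (5.04), CCL4 (4.71), IL1B (4.43), IER3 (3.93), MMP7 (2.82), PLAU (-2.24) and ANKRD55 (-5.25). Larger were those of GSG1 (10.35), DLX3 (10.13), TREML1 (7.52), CD22 (5.11), IL31RA (-8.32), TTK (-4.18) and ECT2 (-2.98), each of the 16 by more than 1.5-fold on the linear scale. The other 12 lists did not pass with all arrays either, with adjusted p from 0.0681 to 0.863. Without DMSO microvesicle array 2 the unfolded protein response (adjusted p = 0.0578) and lipid efflux (0.0508) lists missed the threshold, and without array 3 the lipid efflux list did (0.0539). With the replicate number as a block the unfolded protein response list missed it as well (adjusted p = 0.0662). Over 20 alternatives each, these lists ranged from 0.00139 to 0.25 and from 0.00361 to 0.316.

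In total 1547 of 14077 genes passed, 630 up and 917 down, 1317 of them at least 2-fold. With the replicate number as a block, in a fit of only the 2 groups, 15 genes passed and 46 of the 51 named genes called lost their call. The fit of only the 2 groups without the block passed 405. Without replicate 1 of the PMA microvesicle group 7784 genes passed, 3683 up and 4101 down, 1546 of the 1547 among them. The count was 699 without its array 2, 738 without its array 3, and 864, 637 and 551 without DMSO microvesicle array 1, 2 and 3. Nothing in the labels says that the THP1 arrays are separate cultures, so the p-values measure only the spread between these samples.

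The responses of THP1 to PMA and to PMA microvesicles went together across genes. Over 14077 genes the log2 differences correlated at 0.78 (Spearman 0.79), and 1483 of the 1547 genes called with vesicles (95.9%) had the same sign with PMA. In both comparisons 509 genes rose, where chance would give 68.2, and 594 fell, where chance would give 103, and 8 changed in opposite directions. Without replicate 1 of the PMA microvesicle group, 2202 rose in both (chance 780), 2284 fell in both (chance 847) and 86 went in opposite directions, with a correlation of 0.75. RIN2, FNDC1, DLX3, OLR1, ITGB7 and CD36 rose in both, and IL31RA, S100A8, ANKRD55, TTK and ASNS fell in both. The direct test of the difference between the responses called 120 genes, 24 with the larger value after vesicles and 96 with the smaller. The collagenase MMP1 (-7.97 ± 0.35), GNLY (-7.96 ± 1.03) and APOD (-6.85 ± 0.37) rose with PMA and did not pass with vesicles, but without replicate 1 GNLY rose by 2.59 ± 0.61 with vesicles (adjusted p = 0.00754). ZAR1 (-6.39 ± 0.99) rose by 2.54 ± 0.70 with PMA and fell by 3.86 ± 0.70 with vesicles. TMEM163 (6.66 ± 0.50), AP3B2 (6.47 ± 1.06), ANKRD34C (5.02 ± 0.40) and EBF2 (4.84 ± 0.28) were relatively higher, although 1 of the 2 probe sets of AP3B2 was lower. The interferon list was lower in this difference, with 0 up and 1 down of 23 members, 1 and 5 when adjusted over the list alone (median -1.34, adjusted p = 9.88e-06, and adjusted p = 0.262 with an estimated correlation). Cholesterol synthesis (median 0.66), the unfolded protein response (0.43) and heat shock genes (0.48) were higher, with 0 members called in each. They had adjusted p of 0.00269, 0.00269 and 0.00533 and adjusted p = 0.647, 0.133 and 0.293 with an estimated correlation. Without replicate 1 of the PMA microvesicle group the cholesterol and heat shock lists missed the threshold, each with adjusted p = 0.322, and without DMSO microvesicle array 2 the cholesterol list did (0.0501). Over 24 alternatives each, they ranged from 1.32e-08 to 0.647 and from 2.66e-05 to 0.322. With the replicate number as a block 76 genes differed and ZAR1 lost its call (adjusted p = 0.0658). The adhesion (adjusted p = 0.0457) and metallothionein (0.0191) lists, which had missed the threshold, were then lower, within 0.00642 to 0.549 and 8.97e-05 to 0.647 over their alternatives. Without single arrays the count was 712 or 70 (PMA microvesicles 1 or 3), 44 or 40 (DMSO microvesicles 2 or 3), 66, 62 or 55 (PMA 1, 2 or 3) and 74 or 56 (DMSO 2 or 3).

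**Figure D4:**
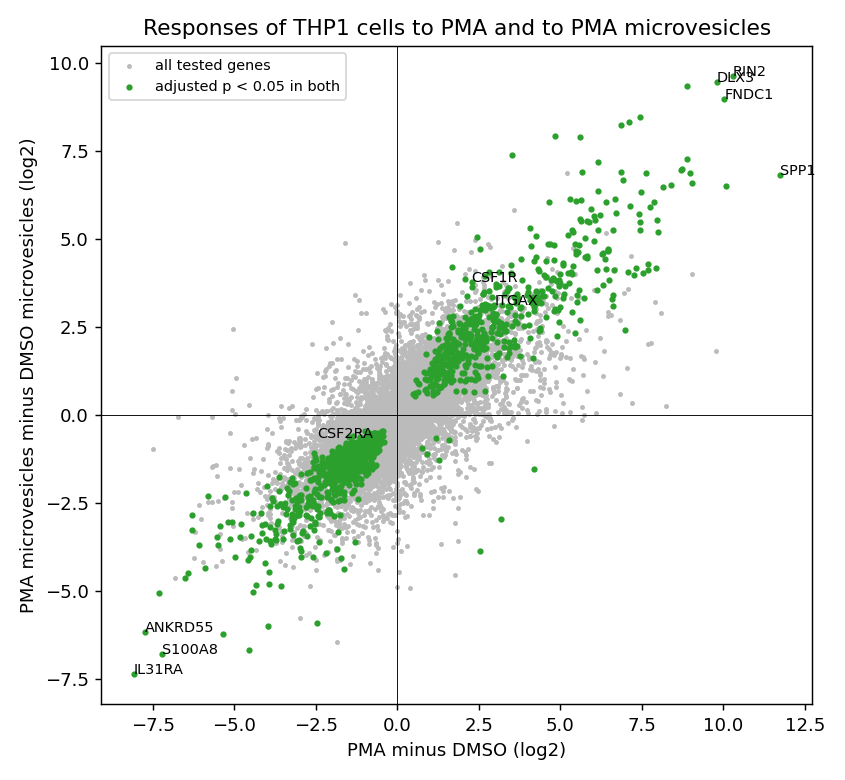
Log2 difference with PMA (horizontal axis) against log2 difference with PMA microvesicles (vertical axis) in THP1 cells, for each tested gene. Green points passed an adjusted p below 0.05 in both comparisons of 3 against 3 arrays.

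Microvesicles of DMSO-treated cells were examined by comparing THP1 cells given DMSO microvesicles with the DMSO cells that had shed them. No group held new THP1 cells without vesicles, so effects of vesicles, of the solvent and of culture cannot be told apart here. Genes that rose were NEK3, a cell cycle kinase (5.69 ± 1.04), POGLUT2 (5.19 ± 0.44), PLPPR4 (4.99 ± 0.52), the protease inhibitor SERPINB10 (4.86 ± 0.48), the mitochondrial lipid kinase AGK (4.80 ± 0.38) and TTC5 (4.61 ± 0.74), all SE with n = 3 against 3. The zinc transporter TMEM163 (-6.62 ± 0.36), SCG3 (-6.34 ± 1.12), AP3B2 (-5.55 ± 0.75), ANKRD34C (-5.06 ± 0.28), EBF2 (-4.89 ± 0.20) and PRG2, an eosinophil granule protein (-4.25 ± 0.66), fell. CSF1R fell by 2.07 ± 0.38, and ITGAM (-0.24 ± 0.26), ITGAX (difference within 0.01, SE 0.24), CSF2RA (-0.35 ± 0.26) and MYC (0.74 ± 0.25) did not pass. TMEM163, AP3B2, ANKRD34C and EBF2, relatively higher in the difference of responses above, read high in the DMSO donors, TMEM163 at 9.06 ± 0.89 (SD, n = 3) against 2.43 ± 0.08 with DMSO microvesicles.

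The lysosome list was lower with 1 of 21 members called, NEU1 at -1.81 ± 0.33, and 6 when adjusted over the list alone (adjusted p = 3.2e-06, and adjusted p = 0.48 with an estimated correlation). The heat shock list was lower with 1 of 10 called, the chaperone DNAJB1 at -0.76 ± 0.14, and 3 when adjusted over the list alone (adjusted p = 7.34e-05, and adjusted p = 0.219 with an estimated correlation). Immediate early genes (median -0.66, adjusted p = 0.000567) and cholesterol synthesis (median -0.60, adjusted p = 0.000197) were lower and metallothioneins higher (median 1.05, adjusted p = 0.000567), with 0 members called, and 1 metallothionein when adjusted over the list alone. Each of these 3 had adjusted p = 0.509 with an estimated correlation. Matrix proteases were lower with 0 of 15 called and 4 when adjusted over the list alone, at an adjusted p of 0.0268 and adjusted p = 0.509 with an estimated correlation. They missed the threshold with adjusted p = 0.0748 without replicate 1 of the PMA microvesicle group and adjusted p = 0.165 with the replicate number as a block (range over 20 alternatives 0.000207 to 0.521). Macrophage markers had 0 of 18 called (adjusted p = 0.834), and the other 20 lists did not pass either, with adjusted p from 0.0865 to 0.972. In total 154 of 14077 genes passed, 105 up and 49 down. With the replicate block, in a fit of only the 2 groups, 1 gene passed, and 14 of the 15 named genes called, SCG3 being the exception, lost their call. The fit of only the 2 groups without the block passed 249. The count was 52 without DMSO microvesicle array 2, 52 without array 3, 100 without DMSO array 2, 71 without DMSO array 3, and 469 without replicate 1 of the PMA microvesicle group. Without that replicate 5 lysosome, 3 heat shock, 3 matrix protease and 1 immediate early gene fell, and platelet markers were called lower (adjusted p = 0.0431).

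In primary cells the responses to GM-CSF and to macrophage microvesicles showed little relation across genes. Their log2 differences correlated at 0.003 over 15251 genes (Spearman 0.14), a Pearson value whose sign changed with single arrays left out, from -0.15 without recipient array 1 to 0.13. Of the 118 genes called with vesicles 41 had the same sign with GM-CSF, and 77 the opposite sign. Of those called in both comparisons, 6 rose in both (chance 11.6, Fisher p = 0.067), 8 fell in both (chance 15.5, p = 0.0282) and 16 went in opposite directions. The difference of the responses passed the test for 4074 genes, 1340 higher and 2734 lower with vesicles. Relatively higher with vesicles were IFITM1 (11.33 ± 0.63), NAPSB (11.31 ± 1.44), CXCL10 (10.25 ± 0.92) and IFI44L (10.14 ± 0.86), and relatively lower were the retinoic acid enzyme ALDH1A2 (-12.87 ± 2.48), SPP1 (-11.46 ± 0.87), the fusion protein DCSTAMP (-11.22 ± 1.61) and GPNMB (-10.92 ± 0.92). SPP1 read 14.06 ± 1.55 (SD, n = 3) in the recipient arrays before any vesicles. Of the interferon list 18 of 23 members were relatively higher, 19 when adjusted over the list alone (adjusted p = 2.91e-11, and adjusted p = 0.149 with an estimated correlation). Of the macrophage list 16 of 25 were relatively lower (adjusted p = 6.13e-08, and adjusted p = 0.0981 with an estimated correlation). The 2 responses were labelled with different kits, whose effect cancels only if it is additive on the log2 scale. With each array centred on its median, which moved the median of all genes from 0.05 to -0.17, the split was 808 and 3284, and with quantile normalization 1770 and 1956. Macrophage microvesicles in primary cells and PMA microvesicles in THP1 gave log2 differences that correlated at -0.11 over 13121 genes (Spearman -0.20). There were 2 genes up in both (IFITM1 and WHRN, chance 1.85) and 3 down in both (CCNB2, HMGB3 and EIF1B-AS1, chance 3.97), all named after their values were seen. That value lay between -0.23 and 0.07 with single arrays left out, the highest without recipient array 1.

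**Figure D5:**
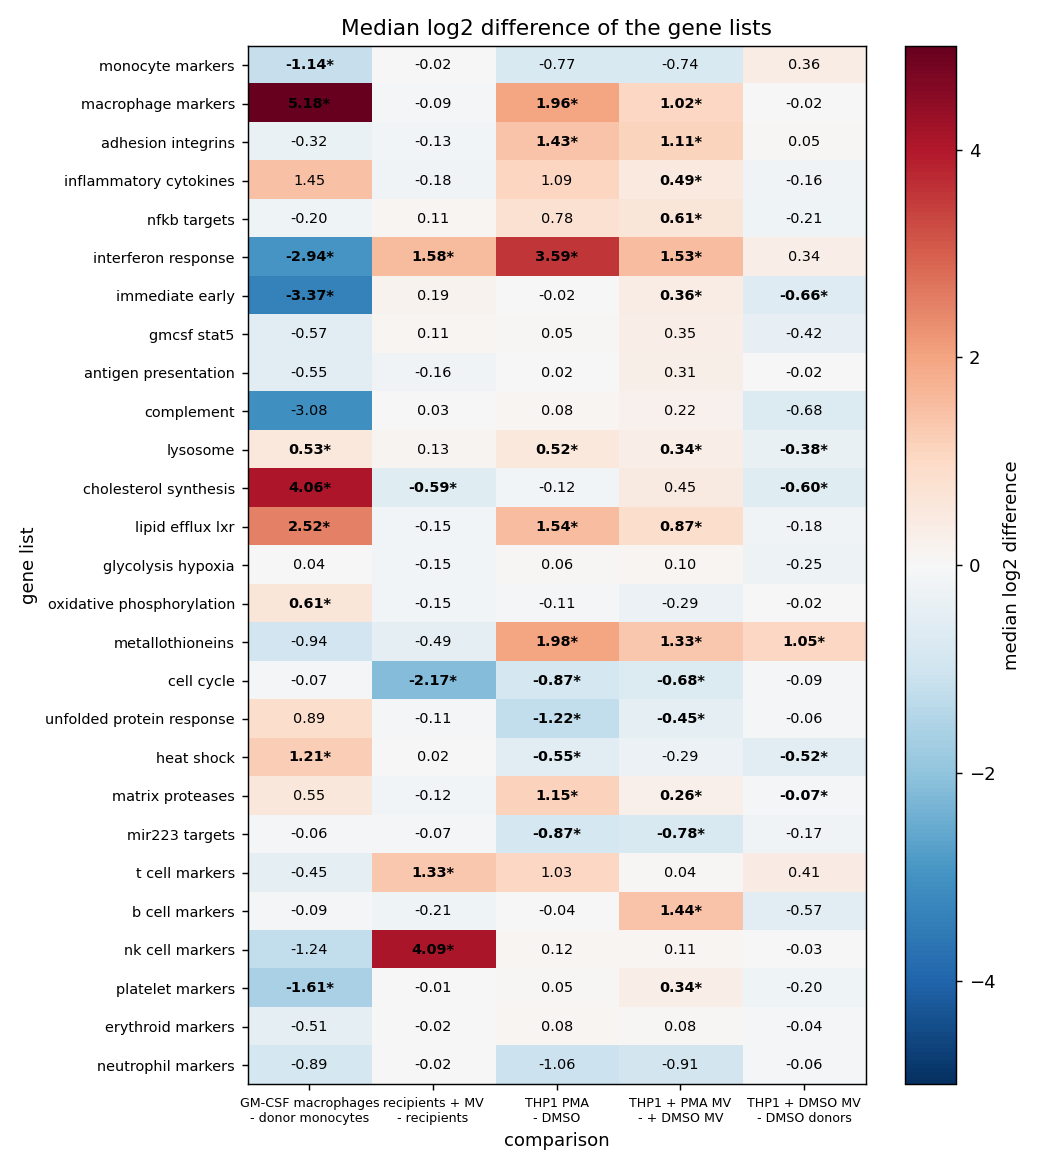
Median log2 difference of the measured members of each of the 27 gene lists (vertical axis) in the 5 main comparisons (horizontal axis), with the value printed in each field. A star marks an adjusted p below 0.05 with the preset correlation between genes, and MV stands for microvesicles.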

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

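The differences of responses and the splits of the arrays were planned, while the tests of explanations for the 3 patterns (recipient arrays, replicate 1 with PMA microvesicles, natural killer cell markers) and the splits within replicate numbers were chosen after these results were seen.

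Macrophage markers read high in the arrays titled as recipient monocytes, with a median of 6.48 log2 above donor monocytes over 25 markers. An effect of the labelling kit as the whole cause is argued against: 100% of 10000 lists matched on the donor level had a lower median difference (median 1.60, highest 4.00), and 10 markers above log2 9 in recipients lay below 3 in THP1 cells with DMSO labelled with the same kits. Monocytes differentiated before lysis are a candidate explanation, since 16 of the 17 markers that rose with GM-CSF reached at least the GM-CSF macrophage mean less log2 2. Of them 13 lay within log2 2 on both sides, and 22 of 25 lay within log2 2 of the vesicle-treated cells. With the median of all genes in recipient minus donor arrays, 1.23, taken off, the first 2 counts were 15 and 14. That median joins kit, donors and cell state. The upper quartile was 6.84 to 6.93 in GM-CSF macrophages and 9.06 to 9.07 in recipient arrays, so 1.23 may be too little for high signals. The treatment field of these arrays names differentiated macrophages as well. Other donors, time in culture or macrophage RNA in the samples stay open, and which label is right was not tested.

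In replicate 1 of THP1 with PMA microvesicles the genes that rose most with PMA stood lower than in replicates 2 and 3, but not every group did, since leaving it out lowered SPP1 from 6.80 to 5.23, CCL4 from 5.51 to 4.71 and the interferon median from 1.53 to 0.55. A wrong label on an array with DMSO microvesicles is argued against, since the 305 genes that rose at least 16-fold with PMA lay 2.03 log2 (median) above the DMSO microvesicle arrays, against 4.03 and 3.56 in replicates 2 and 3. The same median for each DMSO microvesicle array against the mean of the other 2 was at most 0.07 in absolute value. It measures an offset of the array and not the spread of single genes. RNA of cells with DMSO microvesicles mixed into the array cannot be told apart from a weaker response: a first test was undecided, with 57 of these genes over log2 1 above every other array of both microvesicle groups, against 34 and 7. In a second test, tried because of that, 239 genes that fell with PMA had a median of -1.39 where mixing allows -0.74, but only 6 of 9 gene thresholds gave a drop beyond that limit, and the limit assumes a signal linear in RNA. RNA degradation cannot be told apart either, since its ACTB difference between 3' and 5' probe sets, 1.37, lay above replicates 2 and 3 (0.77 and 0.74) but not above every THP1 array with DMSO (1.03 or more), and that of GAPDH, 0.51, lay just above every other THP1 array (next 0.48), while a smaller dose of vesicles or another stage of the response may also account for it and was not tested.

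Natural killer cell markers were higher with macrophage microvesicles, with a median of 4.09 log2 over 11 markers. A lower share of monocytes cannot be excluded, since it would raise the markers of another cell type only where such cells are present. B cell markers did not rise alike, with a median of -0.21 (SE of the mean across markers 0.40) against 4.09 (SE 0.91). With single arrays left out they ran from -1.12 (without recipient array 2) to 0.65 (without vesicle-treated array 2) against 3.48 to 4.11. Whether the samples held B cells was not tested, and T cell markers, with a median of 1.33, went with that explanation. RNA of natural killer cells in these cultures cannot be told apart from induction in the recipient cells: 8 of 11 markers were higher in all 3 arrays than in all 3 recipient arrays, where chance gives 5% of genes, but either would give that. RNA carried in the vesicles of GM-CSF macrophages cannot be told apart either, since the vesicles were not measured: the markers that rose lay 3.65 log2 (median) lower in GM-CSF macrophages, at a near-background level of 2.53, than in vesicle-treated cells (6.92). These 2 groups were labelled with different kits, and the median of all genes was 1.23 higher in recipient than in donor monocytes. That shift was not taken off here. GNLY also rose by 9.77 with PMA in THP1, a line without other cell types. The natural killer cell list did not pass there with PMA (camera adjusted p = 0.326) or with PMA microvesicles (0.665), so this gene alone decides nothing. An effect of time in culture was not tested.

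The response to macrophage microvesicles differed from the response to GM-CSF for 4074 genes. Lists with higher values for microvesicles were natural killer cell markers (median 4.69), interferon response (4.64), immediate early genes (3.73), complement (1.88), monocyte markers (1.74), T cell markers (1.65), platelet markers (1.22), GM-CSF and STAT5 (1.10) and erythroid markers (0.49). Lower were macrophage markers (-5.45), cholesterol synthesis (-4.50), lipid efflux (-3.25), the cell cycle (-3.01), heat shock (-1.23), the unfolded protein response (-0.92), oxidative phosphorylation (-0.87) and the lysosome (-0.35). Their adjusted p ran from 2.91e-11 to 0.0477, and from 0.0972 to 0.691 with an estimated correlation. Over 24 alternatives the unfolded protein response passed in 8, the lysosome in 9, and oxidative phosphorylation and platelet markers in 16 each. Among these lists, immediate early genes, complement, monocyte markers and macrophage markers did not pass with vesicles (camera adjusted p = 0.273, 0.791, 0.949 and 0.949). Their medians with GM-CSF were -3.37, -3.08, -1.14 and 5.18, so these differences come mainly from the GM-CSF side. Labelling kits differ between the 2 responses, the recipient arrays already carried macrophage markers, and the vesicle response includes 24 h in culture. The genes furthest apart were IFITM1 (11.33), NAPSB (11.31), CXCL10 (10.25) and IFI44L (10.14), and ALDH1A2 (-12.87), SPP1 (-11.46), DCSTAMP (-11.22) and GPNMB (-10.92).

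The response of THP1 to PMA microvesicles differed from that to PMA for 120 genes, with medians of -1.34 for the interferon response, 0.66 for cholesterol synthesis, 0.43 for the unfolded protein response and 0.48 for heat shock. With an estimated correlation none of the 4 passed (adjusted p = 0.262, 0.647, 0.133 and 0.293), and without replicate 1 cholesterol synthesis (0.13) and heat shock (0.19) missed the threshold, each with adjusted p = 0.322. The genes furthest apart were TMEM163 (6.66), AP3B2 (6.47), ANKRD34C (5.02) and EBF2 (4.84), and MMP1 (-7.97), GNLY (-7.96), APOD (-6.85) and ZAR1 (-6.39).

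Of 100 drawn splits of 12 arrays, 1, the real one, called as many genes for each difference of responses (4074 against at most 2013 in the other splits, and 120 against at most 6). These splits mix groups that differ widely, which widens the spread within the drawn groups. They therefore cannot exclude chance for the difference of the responses itself. With labels permuted within the numbers, 2 of 100 splits in primary cells and 3 of 100 in THP1 called as many, the real one included. These shares lie below 0.05, but most of these splits mix groups too and have the same limit. The highest others, 11459 and 5346, kept the groups whole and so compared the real groups in another way, which points to a structure of the samples. Splits that mixed groups called at most 833 in primary cells and 1566 in THP1, the latter above the real 120. For the comparisons of 3 with 3 arrays, 10 splits are too few for a share below 0.05. The real split and the highest other called 6976 and 0 genes with GM-CSF, 118 and 123 with macrophage microvesicles (2 of 10 splits called at least as many), 3111 and 1 with PMA, 1547 and 3 with PMA microvesicles, 154 and 4 with DMSO microvesicles, and 11946 and 2 for recipient against donor monocytes. Among the splits that part all 3 pairs, as the real one does, the highest other was 0 with GM-CSF, 3 with PMA microvesicles and 0 with DMSO microvesicles, and the split that called 4 genes with DMSO microvesicles kept a pair together.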

How the results depend on the processing

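The alternatives were planned, except the omission of replicate 1 of THP1 with PMA microvesicles from comparisons that do not use it. Signal near background limits the values below log2 3, and 3 arrays per group limit the spread estimates. Over the alternatives run, named genes kept their direction and side of the threshold in 3932 cases, lost the call in 499, gained it in 8 and turned in 8. Named genes that kept both under each alternative run for them were 30 of 44 with GM-CSF, 3 of 24 with macrophage microvesicles, 26 of 49 with PMA, 2 of 52 with PMA microvesicles, and 8 of 23 with DMSO microvesicles. They were 7 of 8 and 5 of 8 for the differences of responses in primary cells and THP1, and 11 of 18 for recipient against donor monocytes. Lists kept their state in 3546 cases, lost the call in 227, gained it in 168 and turned in 2. The fit of only the groups compared was not run for the differences of responses, as it is identical. The cause was not tested, except that stricter thresholds pass fewer genes and single probe sets test more features.

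Counts of called genes moved as follows, in the order GM-CSF, macrophage microvesicles, PMA, PMA microvesicles, DMSO microvesicles, differences in primary cells and in THP1, and recipient against donor monocytes. The main counts were 6976, 118, 3111, 1547, 154, 4074, 120 and 11946. With every probe set tested by itself they were 11111, 439, 5475, 2552, 235, 6716, 191 and 23503, and with an adjusted p below 0.01, for the first 7, 4287, 54, 1327, 476, 59, 2173 and 38. A 2-fold minimum left 4278 with GM-CSF. The mean of probe sets gave 183 with macrophage microvesicles, and the 60th percentile gave 78 and an intensity trend with a robust prior 79 for the difference in THP1. With only the groups compared in the fit limma called 7 with macrophage microvesicles, 4722 with PMA, 405 with PMA microvesicles and 249 with DMSO microvesicles, and with all 24 arrays in a fit 182, 3543 and 411 with macrophage, PMA and DMSO microvesicles and 250 for the difference in THP1. With both groups titled as fresh monocytes as the control 9838 genes were called with macrophage microvesicles. Single arrays left out gave 5053 to 5951 with GM-CSF, 106 to 469 with macrophage microvesicles, 1764 to 2434 with PMA, 551 to 7784 with PMA microvesicles, 52 to 141 with DMSO microvesicles, 3150 to 5086 and 40 to 712 for the differences and 10854 to 11853 for recipient against donor monocytes. The ends above 1.5 times came without recipient array 3 (469), without replicate 1 of PMA microvesicles (7784 and 712), and without DMSO microvesicle array 3 (551 and 40) or 2 or 3 (52), and the other arrays that moved a count that far are named with the comparisons. Without replicate 1 of PMA microvesicles the count was 5856 with PMA and 469 with DMSO microvesicles.

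With the replicate block limma called 0 genes with macrophage microvesicles (1058 at an unadjusted p below 0.05), 4996 with PMA, 15 with PMA microvesicles, 1 with DMSO microvesicles and 76 for the difference in THP1. The block was fitted with only the groups compared. Its like counts are therefore those of that fit without the block, given above, and not the main counts. For PMA and DMSO microvesicles the numbers were taken to pair the arrays, although the best match had the same number for only 2 of the 3 numbers in each. The numbers are not known to pair the arrays of the first 2, where the array of the other group that correlated best had the same number for 1 and for 2 of the 3 numbers. There the block also moved the lysosome list with macrophage microvesicles (adjusted p = 0.0258, from 0.0529) and, with PMA, the lysosome (0.0716) and matrix protease lists (0.0974). In the difference of primary cells the lysosome and unfolded protein response lists missed the threshold (each 0.0586). With GM-CSF SDHD and NDUFS1 (adjusted p = 0.0675 and 0.0558) and with PMA ICAM1 (0.0537) passed no longer. Apart from these and the calls given with the comparisons, the block changed no other call.

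Of the lists called, 10 with GM-CSF became 16 with every probe set, 5 without probe sets ending in _x_at or _s_at, 17 with all 24 arrays, 0 with an estimated correlation (limma camera) and 19 with fry, and 8 to 13 with single arrays left out. The 5 with macrophage microvesicles became 0 with both monocyte groups as the control, 1 with an estimated correlation, 3 with fry and 4 to 7 with arrays left out. The 11 with PMA became 0 with an estimated correlation, 20 with fry and 10 to 12. The 15 with PMA microvesicles became 6 with all 24 arrays, 8 with DMSO donors as the control, 0 with an estimated correlation and 0 (without replicate 1) to 18. The 6 with DMSO microvesicles became 0 with an estimated correlation, 1 with fry and 6 to 8. The 17 of the difference in primary cells became 10 without _x_at or _s_at probe sets, 0 with an estimated correlation and 13 to 17, and the 4 of the difference in THP1 11 with every probe set, 0 with an estimated correlation and 3 to 6.

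Direction turned for ITGAX with GM-CSF (-0.71 as the mean of probe sets), and with every probe set for ABCA1 (-0.027), SDHD (-0.16) and NDUFS1 (-0.023) with GM-CSF, IGF1R with PMA (1.65), AP3B2 in the THP1 difference (-0.035) and CSF2RA in recipient against donor monocytes (-0.88, and -0.79 with quantile normalization). With both monocyte groups as the control the direction of the test with macrophage microvesicles turned for cholesterol synthesis (median 1.76) and for T cell markers. The median of the T cell markers kept its sign (1.67). The correlation of the GM-CSF and microvesicle responses (0.0025) was -0.00226 without the filter, -0.00171 with quantile normalization, -0.036 without GM-CSF macrophage array 2, -0.038 without vesicle-treated array 1, and from -0.154 without recipient array 1 to 0.131 without recipient array 2. That of macrophage and PMA microvesicles (-0.11) was 0.00988 over genes called in either, and from -0.229 without recipient array 2 to 0.0739 without recipient array 1. That of PMA and PMA microvesicles (0.78) lay between 0.747 and 0.816 with single arrays left out.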

Other observations

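The responses of monocytes to GM-CSF and of THP1 to PMA were set side by side, a comparison chosen after the data were seen. Macrophage markers rose in both, 17 of 25 with GM-CSF (median 5.18) and 10 of 18 with PMA (median 1.96), with SPP1 and the receptor OLR1 among them. Interferon response genes fell with GM-CSF (18 of 23) and rose with PMA (14 of 23). Cholesterol synthesis rose with GM-CSF (13 of 15) and had 0 of 15 genes called by limma with PMA (median -0.12, adjusted p = 0.519). Cell cycle genes fell in 13 of 25 cases with PMA and had 4 up and 1 down of 24 with GM-CSF (adjusted p = 0.275). The list calls with GM-CSF and PMA were lost with an estimated correlation, with adjusted p from 0.0982 to 0.374. Over 13121 genes the log2 differences correlated at -0.19 (Spearman -0.34), and 212 genes rose in both (chance 358, Fisher's exact p = 5.65e-23 across genes), 188 fell in both (chance 344, p = 4.72e-27) and 889 changed in opposite directions. Cells, kits and culture differ between the 2 responses, and the difference itself was not tested.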
